A study of Mus musculus with 8 samples.

How the data were processed

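Bone marrow cells of mice were differentiated into macrophages for 7 days in medium conditioned by L929 cells, a fibroblast line that secretes the macrophage growth factor M-CSF. They were then kept for 24 h in 10 nM insulin, 25 mM glucose and 250 uM palmitate (C16:0), a treatment that loads macrophages with saturated fatty acid. Polyadenylated RNA of 8 libraries was sequenced, 4 from control cells and 4 from knockout cells. Both groups carried loxP-flanked alleles of 2 miRNA clusters, Mirc11 and Mirc22, which encode miR-23, miR-27 and miR-24. Only the knockout group carried the Cre recombinase gene, on both copies of Lyz2, a gene active in myeloid cells. Groups were taken from the sample labels alone. The labels do not state that the libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be partly technical.

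Per the submitters' processing notes, FastQC, cutadapt, Salmon and DESeq2 were used with the mm10 build. Versions, settings and the roles of these tools are not given in the sources used here. The deposited comparison gives each gene 4 kinds of value, per the file headers. The signal is the authors' mean normalized count over all libraries. The effect is the authors' log2 fold change with its standard error, also in log2 units. The score is the authors' Wald statistic, which equals the log2 fold change divided by its standard error to within 1.1e-07. The p-value and adjusted p-value are the authors', per the file headers, and a Benjamini-Hochberg adjustment recomputed from the deposited p-values differed from the deposited adjusted p-values by at most 5.7e-09.

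Normalized values per library occupy 8 further columns, numbered in a way that matches no sample label, so they were not used in any step. Giving them a group would have needed column order or measured values. The planned limma fit on values per library, its refits without single libraries or with a replicate block, array weights, other pseudocounts and rescalings, the edgeR and DESeq2 refits, an estimated correlation between genes, other splits of the samples and the comparison of replicates were therefore not run. Depth per library is unknown here for the same reason, and no interval for counting error is given. Gene calls are the authors' own, at an adjusted p under 0.05, and no replicate-level check of a gene was possible.

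The header of the deposited comparison does not say which genotype is the numerator. The sign was read from Lyz2, whose 2 copies carry the Cre insertion in the knockout, and negative values were taken as lower in knockout. All directions given here rest on that reading, and Lyz2 is therefore no independent check of the labels.

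The table lists 15853 genes, of which 15849 have a p-value and 14619 an adjusted p-value. Among genes with a p-value but no adjusted p-value, the mean normalized count was at most 3.75. Positions came from GENCODE M21 (GRCm38, the assembly of mm10), in which 15187 genes (95.8%) matched 1 annotated gene by symbol. Genes were named by a rule fixed before the data were examined. It took the knockout checks, the 10 largest rises and 10 largest falls past the threshold with a mean of at least 100 in the higher group, up to 4 members per gene list with the smallest adjusted p, Eif4ebp2, and the 3 genes with the smallest p among those with a site for each miRNA. Predicted-gene symbols were left out of the rises and falls. A further condition, that no libraries of the groups overlap, could not be applied, and the group mean was derived from the mean and fold change with equal group sizes. Genes named outside the rule are said to be so.

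Gene lists (41, fixed before the data were examined) were tested on the deposited statistic with cameraPR of limma 3.58.1 in R 4.3.3, a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. This replaces camera on values per library. The test is two-sided and compares a list with all other genes that have an adjusted p-value. For the miRNA test, the longest annotated 3' UTR of each gene was searched for the 7-nucleotide and 8-nucleotide seed matches of the 3 miRNAs, and genes with a site were compared with genes that had none of the 3. The seeds of miR-155, miR-122 and miR-1 served as 3 controls, among genes without a site for the deleted miRNAs. The share of calls near a locus was compared with that of all other genes by Fisher's exact test, two-sided, in Python 3.11.15 with scipy 1.17.1.

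Alternatives comprised other filters on the mean, other kinds of site, adjustment for UTR length and GC content, other windows, ranks or log2 fold changes as the statistic, a preset correlation of 0.05, centring of all fold changes on the total, a joint model of the 6 seeds and a stricter threshold. A further alternative, chosen after seeing the data, left out the stromal list and a second list of stromal genes. The steps were tested on simulated data. For knockout against control, with 14619 genes and 100 simulations, 3.32% of unshifted lists had p under 0.05, and 75.7% of 200 genes changed by a log2 fold of 1 were recovered with 5.21% of calls false. The Lyz2 window test called 4.9% of 1000 unshifted sets among 14048 genes. In all these simulations genes varied independently, so the rates do not cover lists or neighbours whose members vary together.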

Results

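The data compare knockout macrophages, made to lose the Mirc11 and Mirc22 miRNA clusters, with control macrophages, after 24 h of insulin, glucose and palmitate. The groups also differ in Cre itself and in Lyz2, so no change can be assigned to loss of the miRNAs alone. Each genotype had 4 RNA-seq libraries. The series title places the comparison in a study of the miR-23, miR-27 and miR-24 clusters and of lipid-associated macrophage proliferation. Values of single libraries were not used here, so each gene is described by the authors' fold change and its standard error (SE).

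Lyz2, which encodes lysozyme M and carries the Cre insertion, was far lower in the knockout. In the authors' deposited table its log2 fold change was -9.10 (SE 0.42, adjusted p = 6.25e-102 by DESeq2), and this gene sets the direction of every other value. The gene lies at chromosome 10, 117277331 to 117282321 (mm10). Its neighbour and close paralog Lyz1 had a log2 fold change of 1.95 (SE 0.27) in the authors' deposited table, and since reads can be shared between the lysozyme copies that value is uncertain. Aopep, the host gene of the Mirc22 cluster, was at 0.14 (SE 0.11, adjusted p = 0.407) in the authors' deposited table. Fancc, annotated on the opposite strand across the Mirc22 precursors, was called lower, at -0.53 (SE 0.18, adjusted p = 0.0207) in the authors' deposited table. Whether reads were counted by strand is not given in the sources used here, so reads of Fancc and Aopep may not be separated, and Fancc falls outside the naming rule. Mature miRNAs are not captured by poly(A) libraries, and the precursors Mir23a, Mir27a, Mir24-2, Mir23b, Mir27b and Mir24-1 were not analysed here. Deletion of the clusters was therefore not measured. The list of knockout checks passed as lower (adjusted p = 0.0146), a result carried by Lyz2: the median of its members was 0.14, their mean -2.33, and the direction turned under ranks.

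Knockout and control cells differed at 3363 of 14619 genes, 1651 higher and 1712 lower in the knockout, by the authors' adjusted p. Thbs2, Hspg2 and Dpp7 were among the largest rises, and Vsig4 and Ly6e among the largest falls. Of the called genes, 597 rose at least 2-fold and 49 fell at least 2-fold, while 66.8% changed by less than 1.5-fold. The genes called higher had a median mean normalized count of 371, against 2882 for those called lower. Centring the fold changes on the summed group means, a shift of -0.06, gave 2339 genes higher and 960 lower, so that the share called higher was 70.9% in place of 49.1%. The balance of rises and falls thus changed with the scaling. The summed means count abundant genes most and include Lyz2 (mean normalized count 256190), so the shift partly reflects the loss of Lyz2 itself.

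**Figure D1:**
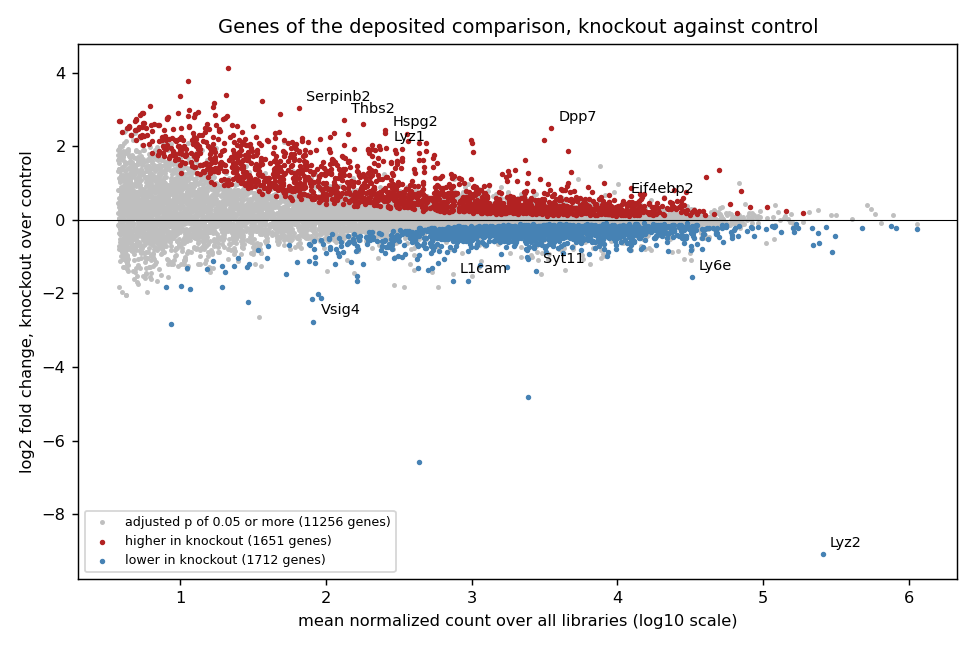
Log2 fold change of knockout over control against the mean normalized count (log10 scale) for 14619 genes of the authors' deposited table, 1 point per gene. Genes past an adjusted p of 0.05 are red (1651 higher) or blue (1712 lower), and Lyz2 lies lowest, at -9.10.

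The 10 largest rises under the naming rule were Serpinb2, Thbs2, Ptprf, Dpp7, Timp3, Gsta3, Hspg2, Col6a1, Slc16a9 and Col6a2. In the authors' deposited table their log2 fold changes ran from 3.03 (Serpinb2, SE 0.54), which encodes a plasminogen activator inhibitor, to 2.25 (Col6a2, SE 0.47), a collagen VI chain. Thbs2, a matricellular thrombospondin, was at 2.70 (SE 0.33) and Hspg2, which encodes perlecan of the basement membrane, at 2.36 (SE 0.26) in the authors' deposited table. Dpp7, a dipeptidyl peptidase of intracellular vesicles, had the smallest adjusted p of these, with a log2 fold change of 2.49 (SE 0.12, adjusted p = 1.48e-89) in the authors' deposited table. Stromal markers rose in the same comparison (16 of 17 called higher, median 1.86). Whether any of these 10 rises came from stromal cells rather than macrophages was not tested.

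Under the naming rule, which leaves out predicted genes such as Gm16867, the largest falls after Lyz2 were those of Vsig4, Dkk2, Tmem178, Slfn1, L1cam, Ear2, Ly6e, Syt11 and Pira12. In the authors' deposited table they ran from -2.77 for Vsig4 (SE 0.48), a complement receptor of tissue macrophages, to -1.36 for Pira12 (SE 0.22). Ly6e was the most abundant of the 9, with a mean normalized count of 32432 and a log2 fold change of -1.56 (SE 0.49) in the authors' deposited table. Slfn1 passed narrowly, at -1.68 (SE 0.66, adjusted p = 0.0496) in the authors' deposited table, and lost its call without a filter (adjusted p = 0.0538) and with centred fold changes (adjusted p = 0.0614).

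Markers of stromal cells and fibroblasts were higher in the knockout. Of 17 measured members, 16 were called higher and 0 lower (17 and 0 adjusted over the list alone), with a median log2 fold change of 1.86 and a camera adjusted p of 6.78e-21. Col1a2, a collagen I chain, was at 2.18 (SE 0.27), Postn, which encodes periostin, at 1.86 (SE 0.22), Acta2, smooth muscle actin, at 1.43 (SE 0.18) and Fbn1, fibrillin 1, at 2.03 (SE 0.26) in the authors' deposited table. The call held at a preset correlation of 0.05 (adjusted p = 1.82e-13).

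Lipid-associated macrophage genes gave no list-level call. Of 27 members, 0 were called higher and 10 lower (1 and 10 adjusted over the list alone), with a median log2 fold change of -0.11 and a camera adjusted p of 0.0588, which passed without a filter (adjusted p = 0.04) and was up to 0.305 under the other alternatives. The fatty-acid binding genes Fabp5 (-0.40, SE 0.08) and Fabp4 (-0.65, SE 0.17), the receptor gene Trem2 (-0.24, SE 0.08) and Gpnmb (-0.23, SE 0.06) were among the 10 in the authors' deposited table. Trem2 falls outside the naming rule and was chosen after its value was seen. The stromal markers, with a median of 1.86, rose in the same comparison.

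Lysosome and autophagy genes were lower as a list: 14 of 38 members fell and 2 rose (14 and 3 adjusted over the list alone), with a camera adjusted p of 0.0146. The 2 members that rose were Gaa, the lysosomal acid alpha-glucosidase (0.87, SE 0.05), and Atp6v1h, a proton pump subunit (0.29, SE 0.06), in the authors' deposited table. Map1lc3a, an autophagosome protein gene, was at -0.45 (SE 0.07) and Tfeb, a transcription factor of lysosomal genes, at -0.33 (SE 0.06) in the authors' deposited table. The call was lost at a mean of at least 50 (adjusted p = 0.0551), at a preset correlation of 0.05 (adjusted p = 0.216), with centred fold changes (adjusted p = 0.0682) and with log2 fold changes as the statistic (adjusted p = 0.134). In the same comparison stromal markers were higher (16 of 17 called, median 1.86) and macrophage identity genes had 3 higher and 9 lower of 24 (camera adjusted p = 0.0715), with Ctss, which is in both this list and the lysosome list, at -0.88 (SE 0.18) in the authors' deposited table.

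Cell cycle genes were shifted upward with almost no single gene called. Of 43 members 40 had a positive log2 fold change, yet 0 were called higher and 1 lower (0 and 1 adjusted over the list alone). The median was 0.51 and the camera adjusted p 0.0146, lost at a preset correlation of 0.05 (adjusted p = 0.216) and with centred fold changes (adjusted p = 0.0682). In the authors' deposited table, Pcna (0.21, SE 0.09, adjusted p = 0.0651), Mcm4 (0.45, SE 0.20, adjusted p = 0.0822) and Bub1b (0.64, SE 0.29, adjusted p = 0.0888), genes of replication and mitosis, missed the threshold. With centred fold changes Pcna (adjusted p = 0.0122) and Mcm4 (adjusted p = 0.0436) passed it. Ccnd3, a D-type cyclin, fell by 0.52 (SE 0.14) on the log2 scale in the authors' deposited table. Alongside this shift, 16 of 17 stromal markers were called higher (median 1.86), and of 24 macrophage identity genes 3 were higher and 9 lower (camera adjusted p = 0.0715).

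Interferon response genes were shifted downward. All 30 measured members had a log2 fold change below 0, and 0 were called higher and 2 lower, also when adjusted over the list alone. The median was -0.74 and the camera adjusted p 0.00889, a call lost at a preset correlation of 0.05 (adjusted p = 0.145). The guanylate-binding protein genes Gbp5 (-0.61, SE 0.16) and Gbp2 (-0.77, SE 0.24) were the 2 called in the authors' deposited table. The standard errors of these members were 6.22 times those of genes of like abundance (median ratio), against 3.07 times for the cell cycle list. Whether the members vary together between libraries was not examined. If they do, the preset correlation of 0.01 gives too small a p. Stromal markers, at a median of 1.86, moved the other way.

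Genes encoded by mitochondrial DNA were higher as a list, with 3 of 13 called higher and 0 lower (3 and 0 adjusted over the list alone). The median was 0.22 and the camera adjusted p 0.0473, which became 0.216 at a preset correlation of 0.05, 0.0624 with centred fold changes and 0.643 with log2 fold changes as the statistic. The authors' deposited table gave mt-Nd4l at 0.56 (SE 0.16), mt-Cytb at 0.35 (SE 0.13) and mt-Nd5 at 0.36 (SE 0.14), all members of the respiratory chain, and mt-Nd5 lost its call without a filter (adjusted p = 0.0531). This rise also came with that of the stromal markers (median 1.86). It did not extend to the separate oxidative phosphorylation list, with 1 member called higher and 7 lower of 43 (1 and 7 adjusted over the list alone). That list had a median of -0.09 and a camera adjusted p of 0.0715, which passed as lower with ranks (adjusted p = 0.0308). Ndufa1 (-0.27, SE 0.05) and Ndufb10 (-0.31, SE 0.08) were among its 7 lower members in the authors' deposited table.

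**Figure D2:**
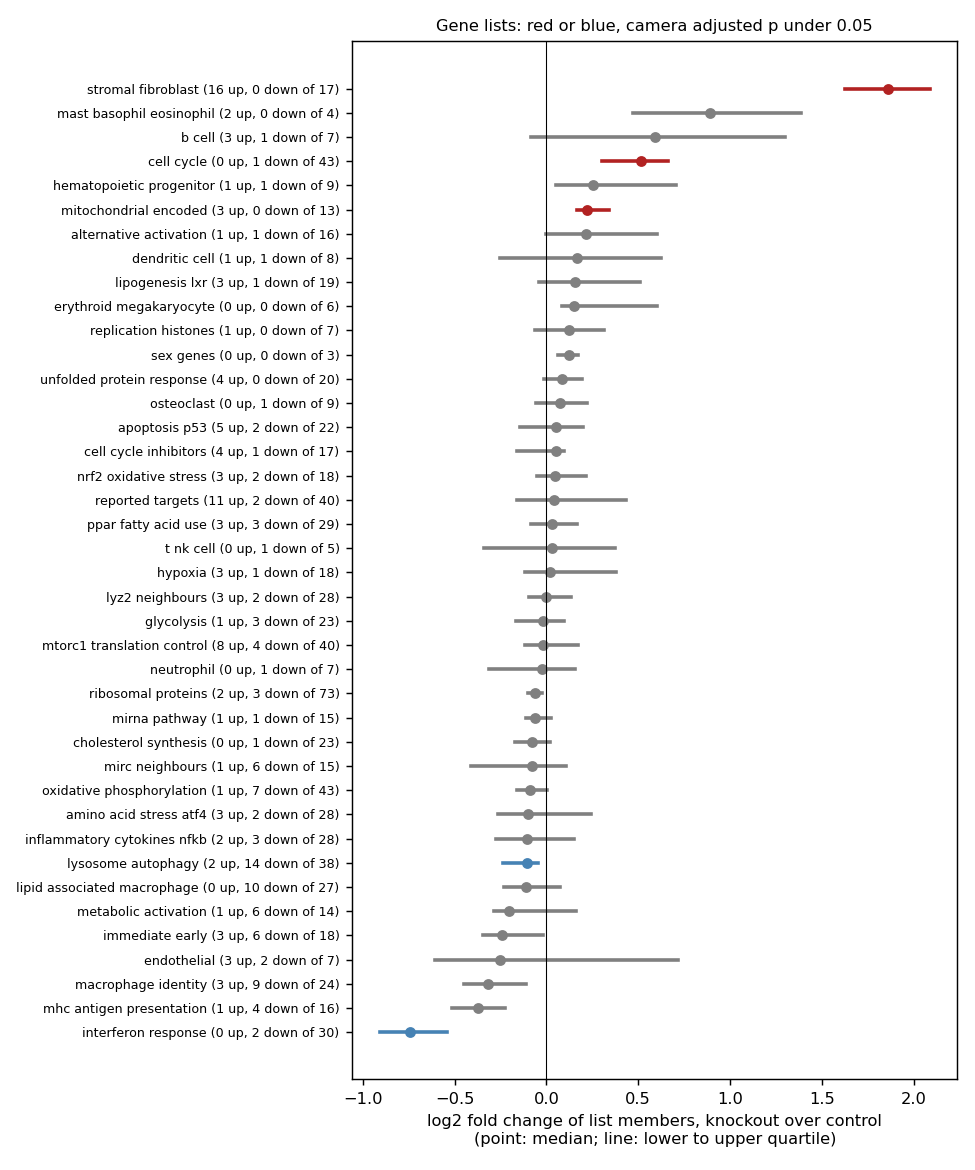
Log2 fold change of knockout over control for the members of each gene list in the authors' deposited table, with the median as a point and the lower to upper quartile as a line. The stromal list lies highest, at 1.86, and the interferon list lowest, at -0.74, and colour marks lists with a camera adjusted p under 0.05.

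Genes with seed matches for the deleted miRNAs were compared with genes without them, to ask whether transcripts that these miRNAs could bind were higher in the knockout. Genes with a miR-23 site (2162) or a miR-27 site (2267) were shifted upward against 7726 genes with none of the 3 sites. Median log2 fold changes were 0.06 for miR-23 and 0.06 for miR-27, against -0.03 for genes without a site, with a camera adjusted p of 0.000597 for each. Genes with a miR-24 site (2486) had a median of 0.02 and an adjusted p of 0.0671, which passed with 8-nucleotide sites alone (adjusted p = 0.00472) and was 0.215 with adjustment for 3' UTR length and GC content. Of the genes with a miR-27 site, 18.7% were called higher and 8.87% lower, against 9.51% and 14.4% of genes without a site. The control seeds of miR-155, miR-122 and miR-1 gave an adjusted p of 0.762 each. Stromal markers also rose in this comparison. With the stromal list and a second list of stromal genes left out, the camera adjusted p was 0.000461 for miR-23 and miR-27. It was 0.057 for miR-24. The miR-23 and miR-27 calls were lost at a preset correlation of 0.05 (adjusted p = 0.266 for both) and with log2 fold changes as the statistic (adjusted p = 0.194 and 0.18). Genes with sites also had longer 3' UTRs, with a median of 2448 nucleotides for miR-23 against 714 without a site and 1706 for the miR-155 control, and with adjustment for length and GC content the adjusted p was 0.0374 for miR-23 and 0.0288 for miR-27.

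**Figure D3:**
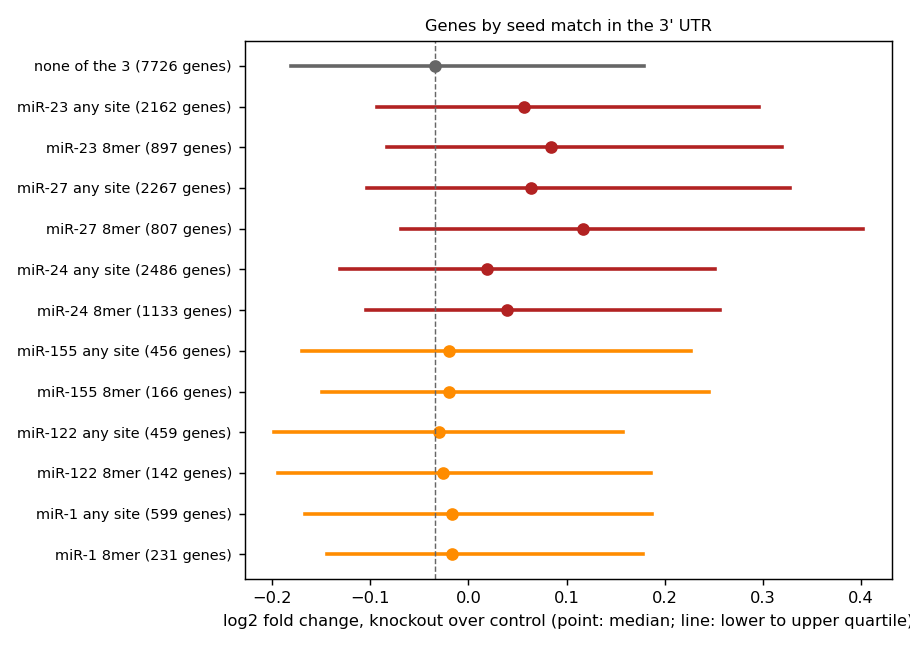
Log2 fold change of knockout over control, median as a point and lower to upper quartile as a line, for genes grouped by seed match in the longest 3' UTR. Genes with 8-nucleotide matches of miR-27 have a median of 0.12, genes with none of the 3 deleted miRNAs' sites -0.03 (dashed), and the control seeds lie near the dashed line.

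Eif4ebp2, which encodes a repressor of cap-dependent translation, was higher in the knockout. Its log2 fold change in the authors' deposited table was 0.52 (SE 0.09, adjusted p = 1.73e-06), a 1.43-fold difference. Its 3' UTR of 5306 nucleotides holds the 8-nucleotide miR-23 match AATGTGAA at chromosome 10, 61431958 to 61431965, on the minus strand in exon 3. A 7-nucleotide miR-24 match lies at 61432964 to 61432970 in the same exon.

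Sesn2, an inhibitor of mTORC1 signalling, was at 0.90 (SE 0.07, adjusted p = 6.85e-40) in the authors' deposited table and has sites for each of the 3 miRNAs. Its miR-23 match AATGTGAA lies at chromosome 4, 132493202 to 132493209, and its miR-27 match ACTGTGAA at 132492425 to 132492432, both in the 3' UTR in exon 10. Ppif, which encodes mitochondrial cyclophilin D, was at 1.13 (SE 0.08) in the authors' deposited table and carries 8-nucleotide matches of miR-23 and miR-27 in exon 6. Zwint, a kinetochore gene with miR-27 and miR-24 sites, was at 1.01 (SE 0.06), C5ar2, a C5a receptor gene with a miR-24 site, at 1.06 (SE 0.06) and Ppm1e, a phosphatase gene with a miR-27 site, at 2.08 (SE 0.13) in the authors' deposited table. The predicted gene Gm16867 has miR-23 sites but was lower, at -6.58 (SE 0.27, adjusted p = 7.61e-125) in the authors' deposited table, and its reads can be shared with related copies. It lies on chromosome 14, away from Lyz2 and both clusters, and the cause of its fall was not tested.

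The list of reported targets of these miRNAs had 11 members called higher and 2 lower of 40 (11 and 4 adjusted over the list alone), with a camera adjusted p of 0.0715. Over the alternatives it ran from 0.0532 at a mean of at least 50 to 0.874 with log2 fold changes as the statistic. Cxcl12 is in both this list and the stromal list, and without the stromal lists the adjusted p was 0.126. The mTORC1 and translation control list had 8 higher and 4 lower of 40 (8 and 4 adjusted over the list alone), with an adjusted p of 0.417, a median of -0.02 and a mean of 0.10. Hmgb2, a chromatin protein gene with a miR-23 match in its 3' UTR, was at 0.98 (SE 0.18), Apaf1, of the apoptosome, at 0.58 (SE 0.11) and Tsc1, an inhibitor of mTORC1, at 0.43 (SE 0.08) in the authors' deposited table.

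Genes near the altered loci were examined because linked strain intervals and deletions can change neighbours. Within 5 Mb of Lyz2, 10 of 36 genes (27.8%) were called, against 23.4% of 14012 other genes (Fisher's exact test, p = 0.554). The Mirc11 precursors lie at chromosome 8, 84208518 to 84208921, and the Mirc22 precursors at chromosome 13, 63300484 to 63301275. Within 5 Mb, 27 of 90 genes (30%) were called around Mirc11 (Fisher's exact test, p = 0.135) and 20 of 84 (23.8%) around Mirc22 (Fisher's exact test, p = 0.898). Of the 27 around Mirc11, 19 were lower, which is 21.1% of the 90 genes against 11.8% elsewhere (Fisher's exact test, p = 0.0129, or 0.17 adjusted over 15 locus windows), a count of calls lower alone that was chosen after seeing the data. Zswim4, 1.8 kb from Mirc11, was at -0.93 (SE 0.14), Ier2, an immediate-early gene, at -0.69 (SE 0.08), Lyl1 at -0.48 (SE 0.12) and the lowly expressed Podnl1 at 2.87 (SE 0.58) in the authors' deposited table. The list of cluster neighbours had 1 member higher and 6 lower of 15 (1 and 6 adjusted over the list alone), with a camera adjusted p of 0.116. Ier2 is also in the immediate-early list, in which 3 members were higher and 6 lower of 18 (4 and 6 adjusted over the list alone, camera adjusted p = 0.0715). Its fall is thus not particular to genes near the cluster.

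**Figure D4:**
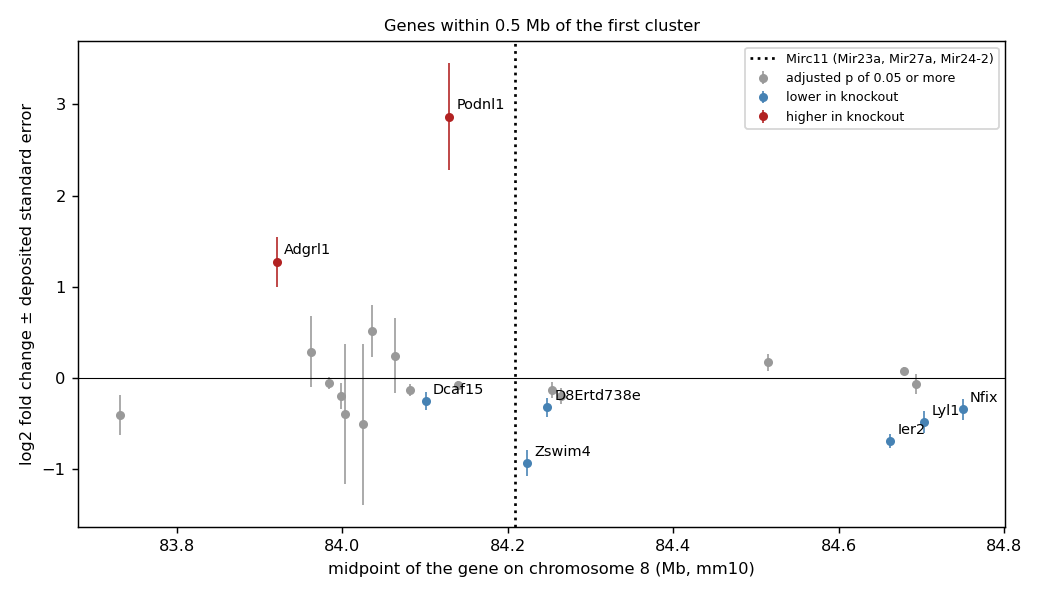
Log2 fold change of knockout over control, with the deposited standard error as bars, against position on chromosome 8 (Mb, mm10) for 23 genes of the authors' deposited table within 0.5 Mb of Mirc11 (dotted line). Zswim4, beside the cluster, is at -0.93, and Podnl1 at 2.87.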

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

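The filters without a minimum and at a mean of 50, the kinds of seed site, the UTR adjustment and the Lyz2 windows were chosen before the data were examined, and all other alternatives here after seeing the data. No paired analysis was possible because the columns of values per library carry no sample, group or replicate number. For the same reason leaving out each replicate, other splits of the samples, array weights, pseudocounts, TMM, quantile and total-sum rescaling per library, a sex covariate, other variance models, edgeR, DESeq2, fry and an estimated correlation were not run, so neither chance splits of the libraries nor dependence on 1 library was examined. Depth per library is unknown.

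Changed genes numbered 3363, and 3258 without a filter, 3062 at a mean of 50, 3373 at a mean of 10 and 3299 with centred fold changes. Under the adjusted p of 0.01 they numbered 2056, with 1047 higher and 1009 lower, since the threshold is stricter. With centred fold changes 960 were lower, since centring adds 0.06 to each log2 fold change.

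Of the lists, 6 passed, against 2 at a preset correlation of 0.05 and 3 with centred fold changes. Leaving aside the knockout checks, which Lyz2 carries, these counts were 5, 1 and 2, and the 1 was the stromal list. The stromal list passed wherever it was tested. Lipid-associated macrophage, p53, oxidative phosphorylation, ribosomal, antigen presentation, macrophage identity, mast cell and B cell lists passed under some alternatives but not in the main test. At the preset correlation of 0.05, adjusted p was 0.216 for the cell cycle, lysosome and mitochondrial lists and 0.145 for interferon. With centring it was 0.0682 for the cell cycle and lysosome lists and 0.0624 for the mitochondrial list. With log2 fold changes as the statistic it was 0.134 for lysosome and 0.643 for mitochondrial genes, and at a mean of 50 it was 0.0551 for lysosome. The cause was not tested. Directions turned for the knockout checks under ranks (0.798), where the size of Lyz2 no longer counts, and for lists that never passed: dendritic cells (0.901 unfiltered, 0.841 at a mean of 50, 0.817 centred), the miRNA pathway (0.99 at a mean of 50, 0.888 centred) and progenitors (0.816 at a mean of 50). Under ranks this held for ATF4 stress (0.639) and endothelial genes (0.998), and with log2 fold changes for ATF4 stress (0.643) and for cell cycle inhibitors, PPAR, unfolded protein, mTORC1 and NRF2 genes (0.98 each).

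For miR-23 and miR-27, adjusted p was 0.266 for both at the correlation of 0.05 and 0.194 and 0.18 with log2 fold changes, and both passed under the other settings. For miR-24 it passed at a mean of 50 (0.0212), with 8-nucleotide sites (0.00472), with the added kind of 7-nucleotide site (0.037), centred (0.0451) and in the joint model (6.48e-07), which takes genes as independent and so understates p. Control seeds never passed, and their direction turned for miR-122 (0.825 with log2 fold changes, 0.695 with 8-nucleotide sites), miR-1 (0.911 with log2 fold changes, 0.865 with the added sites, 0.768 with UTR adjustment) and miR-155 (0.865 with the added sites, 0.722 with UTR adjustment, 0.308 in the joint model). Within 2 Mb of Lyz2 fewer genes were called than elsewhere (Fisher's exact test, p = 0.194). Of 678 results for 175 genes, 654 kept direction and side of the threshold, 15 lost and 7 gained the call, and Kdm5c (0.752) and Tnfrsf11a (0.951) changed sign when centred. The cause was not tested.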

Other observations

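Of the tests in this part, those of the other cell types, of genes within 0.5 Mb of the cluster, of calls lower alone and of the near window against its flank were chosen after the result was seen, as were the settings with ranks, with log2 fold changes as the statistic, with a preset correlation of 0.05 and with centred fold changes. Among gene groups not yet described, cell cycle inhibitors had 4 members called higher and 1 lower of 17, also when adjusted over the list alone (camera adjusted p = 0.374). Ccng1, a p53 target, was at 0.80 (SE 0.09) and Cdkn1c, a cyclin-dependent kinase inhibitor, at 1.15 (SE 0.18) in the authors' deposited table. Macrophage identity genes had 3 higher and 9 lower of 24, also when adjusted over the list alone (adjusted p = 0.0715, and from 0.0045 with ranks to 0.293 at a preset correlation of 0.05). Cd5l, which encodes a secreted macrophage protein, was at 1.34 (SE 0.13), Mpeg1, perforin-2, at -0.44 (SE 0.08) and Ctss, a cathepsin, at -0.88 (SE 0.18) in the authors' deposited table. Antigen presentation genes had 1 higher and 4 lower of 16, or 2 and 7 adjusted over the list alone (adjusted p = 0.162), with B2m at -0.69 (SE 0.23) and H2-D1 at -0.64 (SE 0.17) in the authors' deposited table.

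Of the lipid lists, the lipogenesis and LXR list had 3 members higher and 1 lower of 19, also when adjusted over the list alone (camera adjusted p = 0.221), the PPAR and fatty acid use list 3 and 3 of 29, or 2 and 3 adjusted over the list alone (adjusted p = 0.656), and the cholesterol synthesis list 0 and 1 of 23, or 0 and 0 adjusted over the list alone (adjusted p = 0.609). In the authors' deposited table the cholesterol exporter gene Abca1 was at 0.79 (SE 0.22), Acot1, an acyl-CoA thioesterase, at 1.21 (SE 0.23) and Pdk4, a pyruvate dehydrogenase kinase, at 1.61 (SE 0.31), while Plin2, of the lipid droplet coat, was at -0.21 (SE 0.08), a call lost with centred fold changes (adjusted p = 0.163). NADPH oxidase genes Cybb (-0.45, SE 0.10) and Ncf1 (-0.29, SE 0.08) were lower in the authors' deposited table. The metabolic activation list had 1 higher and 6 lower of 14, or 2 and 8 adjusted over the list alone (adjusted p = 0.166).

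The Y-linked genes Uty and Kdm5d fall outside the naming rule and were chosen after their values were seen. They have no p-value in the authors' deposited table, though their mean normalized counts were 969 and 635. Their log2 fold changes were 0.08 and 0.23, with standard errors of 2.27 and 1.62. Standard errors of this size at such counts show that the fit gave both genes a wide spread, so a mix of sexes within the groups is possible. It was not examined, since values per library were not used. Whether the authors' fit took sex into account is not given in the sources used here, so its part in other calls is unknown.

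For the higher stromal markers, a lower share of macrophages would raise other cell types alike, yet 33 markers of 7 other types, none with a mean above that of the most abundant stromal marker, had a median log2 fold change of 0.37 (upper quartile 0.81), against 1.86 for the stromal list (lower quartile 1.62), which argues against it as the whole cause. It stays open as a part of the cause: 7 of the 33 were called higher and 2 lower, Ebf1 was at 2.86 (SE 0.66) and Gata2 at 2.26 (SE 0.62) in the authors' deposited table, and some of the 33 may also be expressed by macrophages. The mast cell, basophil and eosinophil list and the B cell list had medians of 0.89 and 0.59, with adjusted p of 0.161 and 0.341, from 0.0148 for both with log2 fold changes to 0.312 and 0.447 over the alternatives. Loss of direct targeting was examined in transcripts pooled over the stromal list and the second list described next. Against it as the whole cause, the 43 without a site for the 3 miRNAs had a median of 1.47. The 19 with a site had a median of 1.64. A larger share of stromal cells in the knockout cultures may account for the pattern, and the labels name no sort. Of a second stromal list of 45 tested genes, not among the 41 lists fixed beforehand, 88.9% lay above 0.5. Higher expression of such genes by the macrophages themselves could raise both lists too, so the second list cannot tell these causes apart. Expression by the macrophages was not tested. In the authors' deposited table the most abundant stromal markers, Col1a1 (named after its value was seen) and Col1a2, had mean normalized counts of 1012 and 986.

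The interferon and cell cycle lists were shifted with few members called. Too few reads do not explain it, since 100% of their members had a mean normalized count of at least 100. Their standard errors exceeded those of genes of like abundance, by a median ratio of 6.22 for interferon and 3.07 for the cell cycle. The authors' fit thus gave these genes a wide spread, and for that reason shifts of this size were not called. Which libraries carry this spread, and why, was not examined, as values per library were not used. Nor was it tested whether a larger stromal share, left open above, contributes to these shifts or to the fall of the lysosome list.

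Of 23 genes within 0.5 Mb of Mirc11, 6 were called lower and 2 higher. The share called there was 34.8%, against 23.3% elsewhere (Fisher's exact test, p = 0.216), and between 0.5 and 5 Mb it was 28.4% (Fisher's exact test, p = 0.315). Counting calls lower alone, the shares were 26.1% and 19.4%, against 11.9% elsewhere (Fisher's exact test, p = 0.0478 and 0.0846), and over the whole 5 Mb window 21.1% (Fisher's exact test, p = 0.0129), with 0.0227 at 2 Mb and 0.0489 at 10 Mb. Adjusted over 15 locus windows, the smallest of these was 0.17, and the near window was not shown to differ from its flank (Fisher's exact test, p = 0.557). With no window passing after adjustment, an excess of lower calls near Mirc11 was not shown, and the tests cannot decide on a cause. Both groups carried the loxP-flanked alleles. A strain interval linked to them would lie in both groups unless its extent differed, which was not tested. An effect of the deletion on neighbours was neither shown nor excluded.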
